A study of Bacillus subtilis with 5 samples.

How the data were processed

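Total RNA of B. subtilis 168 (2 samples) and YK240 (3 samples) was hybridised to 2-colour Agilent arrays with 3 probes per gene. Per the labels' protocols, sample RNA was reverse transcribed with random octamers and labelled with Cy3, and a common reference with Cy5. Groups and days were taken from the sample titles. The main values were those of the series' value table, which holds 1 row per gene and 1 column per array on a log2 scale as deposited by the authors. The submitters' processing notes for the 168 samples name Agilent Feature Extraction, R 2.14.1 and RMA, and their role and order are not given in the sources used here. Scale and direction of the table were found by setting each YK240 column against its own array. Across genes the table correlated at r = 0.996 to 0.998 with log2 of the scanner's processed Cy3 signal. With log2 of Cy5 it correlated at r = 0.974 to 0.981, and with the scanner's ratio of Cy5 over Cy3 at r = -0.17 to -0.13. Higher values in the YK240 columns were therefore read as more sample RNA and not as a ratio to the reference. The 168 columns were taken to be on the same scale, which was not checked. Column medians were 11.01 and 10.99 for 168 days 1 and 4, and 11.00, 11.02 and 10.98 for YK240 days 1, 3 and 4. The top value was the same, 17.39, in all 3 YK240 columns, and 17.22 and 17.06 in the 168 columns. How arrays were scaled to one another stays unknown.

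For YK240 the deposited scanner files were also read. Per the file headers they were made with Agilent Feature Extraction 10.7.3.1 and hold Cy3 and Cy5 spot intensity values on a linear scale and a log10 ratio of Cy5 over Cy3, which was used only to check the direction of the table. Scanner files of 168 were not analysed here. The ratio of YK240 to the reference was computed from the spots' median intensities (the files as deposited by the authors have no mean intensity, which had been planned) after normexp background correction with offset 50 and loess within each array, with control spots at weight 0. Spots of a gene were averaged. On the 3 YK240 arrays 79.8%, 77.2% and 78.6% of gene spots were well above background in Cy5 on days 1, 3 and 4. A gene was called not well above background in YK240 if none of its probes was on any of the 3 arrays in Cy3, which held for 578 of 4105 genes. For such a gene the fold is a bound, the mean of 168 against the mean over YK240 arrays of the higher of its own value and the lowest table value of genes with all 3 probes well above background (7.65, 8.48 and 8.28 on days 1, 3 and 4). Depth cannot be given for arrays, and their number limits the precision.

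Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) for YK240 minus 168 over all 5 arrays without covariates, as the series states the design, with Benjamini-Hochberg adjustment over 4105 genes and a threshold of 0.05. No gene was filtered. Locus tags were paired with current symbols and gene neighbours through the RefSeq gene table of assembly ASM904v1, and 4037 genes had a symbol and 68 did not. The build behind the array is not given in the sources used here, so no coordinates are printed. Before the data were examined, 32 gene lists with 737 members were fixed, of which 704 were measured, and were tested with camera at a preset correlation of 0.01, with the correlation estimated, and with fry. List symbols that had been renamed were matched through synonyms. Fixed at the same time was the rule for genes named in the text: sepF, the 10 largest differences in each direction among genes past the threshold whose arrays did not overlap, up to 2 such members of each list, and every early division, late division and xylose gene. Genes named outside this rule are the neighbours given beside sepF, sigB and mtnU in a figure's caption with the other genes drawn there, and those of the closing section, chosen after their values were seen. Chosen in the same way were epsJ, epsK, srfAB and the comG genes, given with the lists.

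The label's day pairs the samples of days 1 and 4. Whether both strains were grown or hybridised together is not given in the sources used here. Strain and any difference between runs can therefore not be told apart. Across genes the difference between days 1 and 4 in 168 correlated with that in YK240 at r = 0.42, and the pairing comes from the labels. The fit with the day as a replicate block was therefore given beside results it changes. Day 3 has no 168 partner, so the blocked differences rest on days 1 and 4. They equal in size those without YK240 day 3. Other alternatives were quantile normalization of the 5 columns, median centring, leaving out the lowest 25% of genes by mean intensity, eBayes with trend or robust, and leaving out each array in turn, for lists also with an estimated correlation. For the reference ratio they were the scanner's processed signals and median centring in place of loess. The YK240 arrays lie on 2 slides, with day 1 on one and days 3 and 4 on the other, and the slides of 168 were not analysed here, so slide was not tested. The fit was tested on simulated data for YK240 against 168, with 4105 genes, normal noise with variances drawn from the fitted prior, and 200 changed genes in each of 20 sets. It recovered 62.5% of 2-fold and 89.8% of 4-fold changes, with 4.45% false among its calls. With the day block it recovered 0.15% and 20.6%, with 8.17% false. Noise of this kind holds neither a day effect shared by the strains nor an array that stands apart. These shares, and the gap between both fits, may therefore not hold for the measured arrays.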

Results

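Transcript levels of 4105 genes of Bacillus subtilis were measured on 5 Agilent arrays. The wild-type laboratory strain 168 was sampled on days 1 and 4 (n = 2), and YK240, a strain that carries sepF under the xylose-inducible Pxyl promoter, on days 1, 3 and 4 (n = 3). SepF is a cytoplasmic cell division protein that binds FtsZ and tethers the division ring to the membrane. The labels do not say whether the days were separate cultures, so that p-values measure the spread between these samples. The 168 cultures were grown in LB at 37 °C with 1.5% xylose and 1 mM IPTG and harvested at an optical density of 0.4 to 0.6. For YK240 the labels list several media and temperatures without saying which was used, so strain and culture description go together. Values are deposited log2 Cy3 intensities, given as mean ± SD over arrays. On the YK240 arrays, 78.5%, 73.9% and 74.6% of the 12315 gene spots were well above background in Cy3 on days 1, 3 and 4, and 0 were saturated. The same measure for 168 was not analysed here, and the number of arrays limits the precision. Across genes, which are not independent replicates, the day 4 array of YK240 stood apart from the other YK240 arrays. It correlated with them at r = 0.976 (day 1) and r = 0.983 (day 3), against r = 0.995 between days 1 and 3 and r = 0.995 between both 168 arrays.

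The comparison of YK240 with 168 asks what else changes in cells that carry the xylose-driven sepF. The sepF transcript (BSU15390) rose from 13.89 ± 0.02 in 168 (n = 2) to 17.39 ± 0.00 in YK240 (n = 3). The difference was 3.50 on the log2 scale (95% confidence interval 3.30 to 3.70), or 11.3-fold (limma, adjusted p = 0.000161). In YK240 sepF was the brightest of all genes on each of the 3 arrays, and its value there, 17.39, was the top value of each YK240 column, which caps the measured fold and leaves no spread between these arrays. The genes beside sepF on the chromosome did not pass the test: ylmE differed by -0.13, ylmD by -0.01, ylmG by 0.04, ylmH by -0.06 and divIVA, which codes for a cell pole protein, by -0.16. The list of 9 sepF neighbours as a group had a median of -0.05 (camera adjusted p = 0.511). With the day as a replicate block, which leaves 1 residual degree of freedom, sepF no longer passed (adjusted p = 0.113).

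Genes for the division machinery were close to their 168 level while sepF was raised. None of the 4 early division genes passed the test. The tubulin homologue ftsZ differed by -0.03 (95% confidence interval -0.23 to 0.17), its membrane anchor ftsA by 0.06 (-0.15 to 0.27), the ring bundling factor zapA by 0.04 (-0.17 to 0.26) and the ring regulator ezrA by 0.03 (-0.31 to 0.37). None of the 6 late division genes passed either. Among them divIB differed by 0.09 (-0.13 to 0.31), ftsL by -0.03 (-0.24 to 0.19), the division transpeptidase gene pbpB by -0.06 (-0.35 to 0.23) and gpsB by -0.05 (-0.30 to 0.20). The widest differences were those of ftsW at 0.20 (-0.02 to 0.43; limma, adjusted p = 0.323) and divIC at -0.28 (-0.58 to 0.03; adjusted p = 0.327). These intervals, from the fit without the day block, exclude changes of 2-fold or more for all 10 genes. Intervals with the block are not given here. Both lists lay near 0, with medians of 0.04 for early genes (camera adjusted p = 0.969) and -0.04 for late genes (adjusted p = 0.717). By the mixed test of fry, which counts shifts in both directions, the late list passed (adjusted p = 0.0485).

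**Figure D1:**
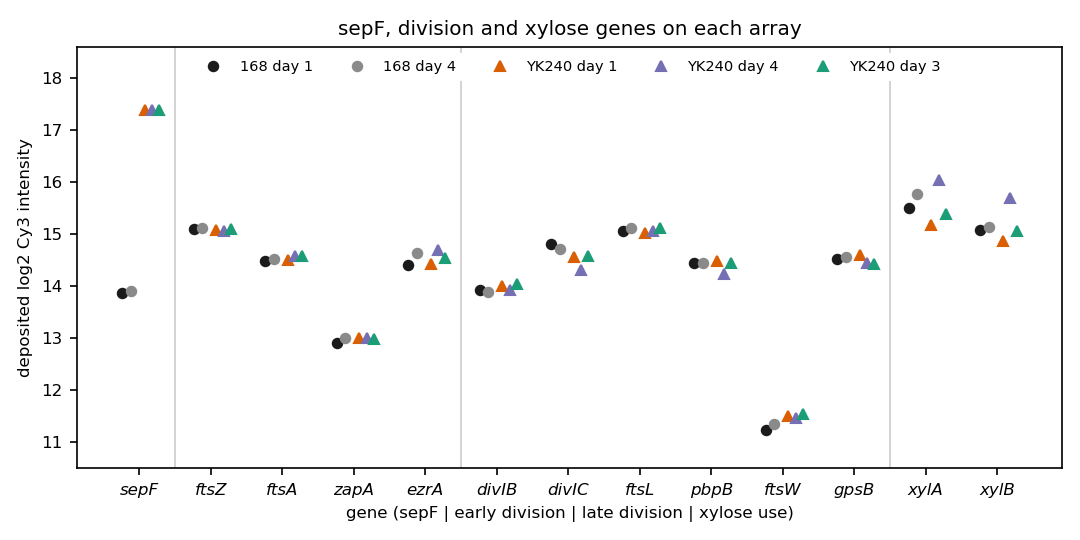
Deposited log2 Cy3 intensity (vertical axis) of sepF, early and late division genes, xylA and xylB on each of the 5 arrays. Circles are 168 and triangles YK240. sepF lies at 17.39 on all 3 YK240 arrays and at 13.89 on average in 168, while ftsZ differed by -0.03.

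Of the xylose genes, xylA and xylB were high in both strains. The isomerase gene xylA stood at 15.64 ± 0.19 in 168 and 15.54 ± 0.46 in YK240, a difference of -0.10 (95% confidence interval -0.86 to 0.66), and lay above 94.6% of genes or more on every array. The kinase gene xylB differed by 0.10 and the repressor gene xylR by 0.04. Values of xynP, xynB and araE were spread widely over the YK240 arrays: xynP was 10.22 on day 1, 10.83 on day 3 and 13.59 on day 4, around a difference of -0.20. xynB differed by -0.18 and araE by -0.08. On YK240 days 1, 3 and 4 araE stood at 5.36, 6.33 and 7.97. Each value lay under that day's floor of genes with all 3 probes well above background, so its difference is uncertain. None of the 6 xylose genes passed the test (list median -0.09, camera adjusted p = 0.748), but without the day 4 array of YK240 the list median was -0.58 and passed camera at the preset correlation (adjusted p = 0.0174; adjusted p = 0.794 with an estimated correlation). In that fit xynB also passed, at -1.09 (limma, adjusted p = 0.0336).

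Across all genes, 104 (2.53%) changed between YK240 and 168, of which 58 were higher and 46 lower in YK240 (limma, adjusted p under 0.05), and 71 changed at least 2-fold, 28 up and 43 down. Of the 43, 7 were not well above background in YK240, and for 6 of these the bound was under 2-fold or could not be given, which leaves 37. At an unadjusted p under 0.05 there were 722. All 104 changed genes had values in which the YK240 arrays lay to one side of both 168 arrays, as did 1506 of all genes (36.7%, against 20% by chance). The number of changed genes was 28 without 168 day 1, 16 without 168 day 4, 41 without YK240 day 1, 22 without YK240 day 3 and 298 without YK240 day 4. With the day as a replicate block it was 0 in limma (526 at an unadjusted p under 0.05). All 104 differences kept their sign, which arrays that do not overlap fix in advance.

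Large rises were in ydcF, ydcG and ydcH, which follow one another directly behind the sigB operon. ydcF rose from 10.57 ± 0.01 to 16.46 ± 0.11, or 59.6-fold, ydcG by 5.12 on the log2 scale (34.7-fold) and ydcH by 5.01 (32.3-fold; limma, each adjusted p = 9.7e-05). After sepF, at 3.50, the next rises were in bmrC and bmrD, the subunits of a multidrug ABC transporter. They rose by 2.84 (adjusted p = 0.00358) and 2.63 (adjusted p = 0.00583). Genes of the surfactin synthetase operon followed, srfAC by 2.35 (5.10-fold, adjusted p = 0.00179) and srfAD by 2.23. comS, a small gene inside that operon whose product protects the competence regulator ComK, rose by 2.17 (adjusted p = 0.00428). The catechol dioxygenase gene catE rose by 2.25 and catD beside it by 2.20 (adjusted p = 0.0479 and 0.0492). The calls of catD and catE were lost when either 168 array, YK240 day 1 or YK240 day 3 was left out, and with robust eBayes. Those of bmrC and bmrD were lost without either 168 array, that of srfAD without 168 day 4 or YK240 day 3, and that of comS without 168 day 4.

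Large falls were in mtnK and mtnA, the methylthioribose kinase and the isomerase of methionine salvage. All 9 mtnA spots of YK240 were not well above background in Cy3, and mtnA was at least 31.4-fold lower than in 168, where it stood at 13.11 ± 0.43 (limma, adjusted p = 0.00124). That bound sets the 168 mean against the lowest table value, per array, of genes with every probe well above background. mtnK stood at 12.30 ± 0.44 in 168 and was well above background with 1 of 9 spots, on 1 of the 3 YK240 arrays. Against the same floor mtnK was at least 17.9-fold lower (adjusted p = 0.000854), so the order of mtnA and mtnK is not known. Then came a block of genes at wapA, which codes for a secreted wall-associated toxin, and wapI, its immunity gene. wapA fell from 16.11 ± 0.07 to 12.78 ± 0.19, a difference of -3.33 (adjusted p = 0.00147), and wapI fell by 3.34 (adjusted p = 0.00128). In the same block yxzC differed by -3.33, yxiF by -3.25, yxiG by -3.10, yxiH by -3.09 and yxiJ by -3.01, and all passed the test. The call of yxiF was lost without 168 day 4 and that of yxiJ without YK240 day 3. ydaC was not well above background on any YK240 array and was at least 1.59-fold lower (adjusted p = 0.0252), a call lost without any array other than YK240 day 4.

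**Figure D2:**
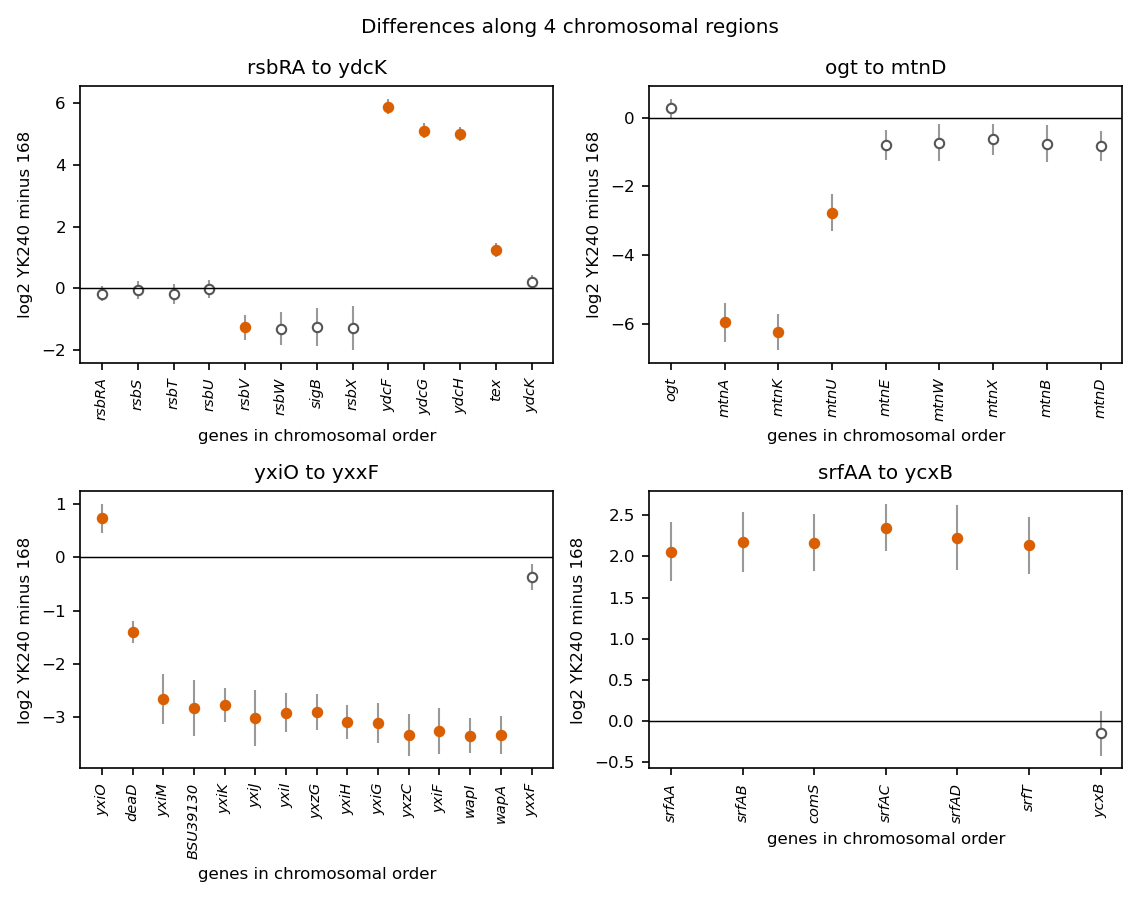
Differences on the log2 scale between YK240 and 168 (vertical axes) for genes in chromosomal order (horizontal axes) in 4 regions. Points are limma estimates with 95% confidence intervals, filled where the adjusted p is under 0.05. ydcF reaches 5.90 beside sigB at -1.24, wapA -3.33 and srfAC 2.35. In YK240 mtnA and mtnU were not well above background, and 1 of 9 mtnK spots was, so their points show no exact difference.

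Of 32 gene lists fixed in advance, 10 shifted by camera with a preset correlation of 0.01, 4 higher and 6 lower in YK240, and 12 of the 104 changed genes were list members. With the correlation estimated per list, 0 of the 32 passed, and by the directional test of fry 1 did, the SigW list. The mixed test of fry passed 9, of which 5 were among the 10. General stress genes driven by SigB were the lowest group. 25 of 27 lay below 0 with a median of -1.30 (camera adjusted p = 2.67e-16; adjusted p = 0.755 with an estimated correlation). Of these, 4 fell past the threshold over all genes and 22 adjusted over the list alone. Named members were the anti-sigma factor antagonist gene rsbV at -1.26 (adjusted p = 0.0329) and yfkJ, a tyrosine phosphatase gene, at -1.19 (adjusted p = 0.0429). The list median was -1.07, -1.17 and -1.65 on YK240 days 1, 3 and 4. Without YK240 day 4, 21 members fell, and without any other single array at most 1 did.

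Genes of the SigW envelope stress regulon were higher, with all 33 above 0 and a median of 0.37 (camera adjusted p = 1.95e-12; adjusted p = 0.695 with an estimated correlation; fry adjusted p = 0.0271). Over all genes 3 rose, and 17 did adjusted over the list alone. ydjI and ydjG rose by 0.89 and 0.88 (limma, adjusted p = 0.0252 and 0.0198). The number that rose was 6 without YK240 day 4 and 0 without any other single array. Genes of iron limitation under Fur had the highest median, 0.80, with all 23 above 0 (camera adjusted p = 2.15e-10; adjusted p = 0.755 with an estimated correlation). Over all genes 0 passed, and 13 rose adjusted over the list alone. Over all genes 7 of them rose without 168 day 1 and 1 without YK240 day 4, and the 168 arrays themselves differed by a median of 0.56 on this list. The competence (ComK) list had a median of 0.41 (camera adjusted p = 0.00156; adjusted p = 0.755 with an estimated correlation). comS was the 1 of 20 that rose, and 3 did adjusted over the list alone. comS lies inside the surfactin operon, where srfAB rose by 2.18, so its rise does not tell ComK apart from that operon. The list was not tested without comS. Without YK240 day 4, on which the median was 0.10, 10 of the 20 rose and the list median was 0.63, against 0.26 without YK240 day 1. The list no longer passed when the lowest 25% of genes by mean intensity were left out (median 0.13, adjusted p = 0.0879). Among its members the comG genes differed by 0.77 to 1.39, and none passed over all genes. Their means lay under 7.65 in both strains, and 7.65 was the day 1 floor of genes with all 3 probes well above background in YK240. The floors of days 3 and 4 were higher, so the sizes of the comG differences are uncertain. Biofilm matrix genes had a median of 0.25 (camera adjusted p = 0.0168; adjusted p = 0.849 with an estimated correlation), with 0 of 20 past the threshold (3 higher and 2 lower past it without YK240 day 4). That call was lost without YK240 day 3 (median 0.16, camera adjusted p = 0.0823) and with the day as a replicate block (median 0.16, camera adjusted p = 0.0906). Both fits rest on the same differences. The 2 members below 0, epsJ at -0.66 and epsK at -0.73, were matched by symbol to BSU04270 and BSU04280. The other eps genes lie at BSU34220 to BSU34370, so these 2 lie outside the matrix operon. The list's counts and camera result include them. The list was not tested without them.

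Purine synthesis genes were lower, with 17 of 19 below 0 and a median of -0.46 (camera adjusted p = 4.45e-07; adjusted p = 0.755 with an estimated correlation). Over all genes 0 passed, and 8 fell adjusted over the list alone, while 1 fell over all genes without YK240 day 4. The median was -0.26, -0.35 and -0.72 on YK240 days 1, 3 and 4. The PBSX prophage list had a median of -0.54 (camera adjusted p = 0.00329; adjusted p = 0.849 with an estimated correlation) but 0.69 on YK240 day 1 against -0.94 on day 3 and -1.38 on day 4, and the 168 arrays themselves differed by a median of 1.41 on this list. It no longer passed without YK240 day 4 (median -0.12, adjusted p = 0.304) or without 168 day 1, where its median was 0.15 (adjusted p = 0.817). The median was -1.25 without 168 day 4 and -1.17 without YK240 day 1. It was -0.35 without YK240 day 3 (camera adjusted p = 0.0474). With the day as a replicate block, which rests on the same differences, the list passed as well. Small shifts were found for wall and lipoteichoic acid synthesis (median -0.16, camera adjusted p = 0.00339) and for ribosomal proteins (median -0.09, adjusted p = 0.00108), each with adjusted p = 0.755 with an estimated correlation and 0 members past the threshold. Without YK240 day 4 the wall list no longer passed (median -0.08, adjusted p = 0.0877), and the ribosomal median was -0.04 (adjusted p = 0.0385). In the sulfur and methionine list (median -0.08, camera adjusted p = 0.00734; adjusted p = 0.755 with an estimated correlation) 2 of 23 fell, mtnA and mtnK. The call was lost without 168 day 1 (median -0.02, adjusted p = 0.0844) or YK240 day 4 (adjusted p = 0.0689). The median was -0.17 without 168 day 4 and -0.04 without YK240 day 1. It was -0.19 without YK240 day 3 and, by the same differences, with the day as a replicate block. The list passed without YK240 day 1 or day 3 and with the block.

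The other 22 lists had medians between -0.45 and 0.09 and did not pass (lowest camera adjusted p = 0.0578). With the day as a replicate block 3 of them passed at the preset correlation: pyrimidine synthesis (adjusted p = 7.08e-07), branched-chain, tryptophan and histidine synthesis (adjusted p = 0.00222) and SigM (adjusted p = 0.0151). Leaving out 1 array brought some past the threshold, among them the xylose and CcpA lists without YK240 day 4, given with their values. The others were pyrimidine synthesis (adjusted p = 0.000108 without YK240 day 3 and 0.019 without 168 day 4), branched-chain, tryptophan and histidine synthesis (without either of these), SigM (without 168 day 4, YK240 day 1 or YK240 day 3), the SOS response (without 168 day 4) and motility (without 168 day 1). DNA replication and chromosome segregation passed with quantile normalization (adjusted p = 0.0436), and the branched-chain list without the lowest 25% of genes (adjusted p = 0.0487). In these fits and in that with the block, the correlation was not estimated. With an estimated correlation 0 of the 32 lists passed whichever array was left out. In the autolysin list lytE, an endopeptidase gene of cell elongation and separation, fell by 1.35 (limma, adjusted p = 0.0173), the 1 of 9 members that changed. In the list of Lia, Bce and Psd antibiotic responses liaH, which codes for a phage shock protein homologue, differed by -0.92 (adjusted p = 0.0272), the 1 of 10 members that changed. The calls of lytE, liaH, rsbV, yfkJ, ydjI and ydjG each held without YK240 day 4 and were lost without any other single array. Carbon genes under catabolite repression by CcpA had a median of -0.08 (camera adjusted p = 0.201), made of -0.89, -0.43 and 1.09 on YK240 days 1, 3 and 4. Without day 4 their median of -0.65 passed at the preset correlation (adjusted p = 1.5e-16; adjusted p = 0.794 with an estimated correlation). For the arginine list the median was 0.02 and the mean 0.14, while camera gave the direction as lower (adjusted p = 0.712).

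**Figure D3:**
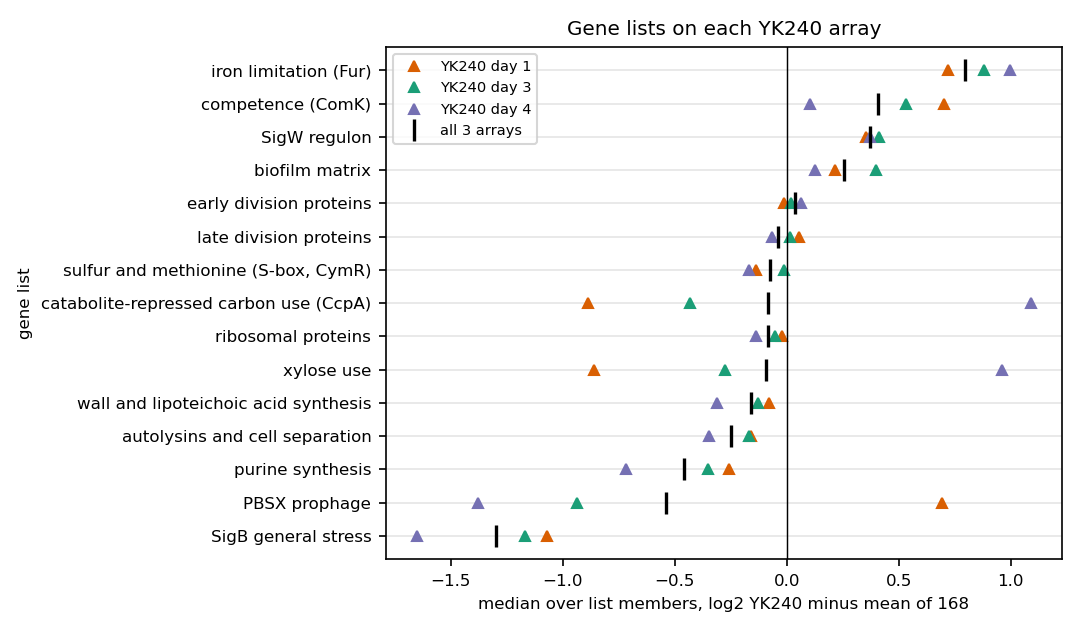
Median log2 difference from the mean of 168 (horizontal axis) over the members of each gene list (vertical axis) on each YK240 array. Triangles are single arrays and bars all 3 arrays. SigB general stress genes lie between -1.65 and -1.07 on the 3 arrays, SigW genes between 0.36 and 0.41, and catabolite-repressed genes between -0.89 and 1.09.

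The YK240 arrays also carried a common reference in Cy5, a pool of samples and strains. Against it, sepF was higher in YK240 by 2.06 ± 0.11 on the log2 scale (SD, n = 3), ydcF by 1.99 ± 0.15 and ydcH by 2.30 ± 0.05. Against 168 these differences were larger, at 3.50, 5.90 and 5.01. Of the 104 changed genes, 96 had the same sign against the reference as against 168.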

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

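Tests in this part were chosen after the results they bear on were seen, except the comparison of the SigB list with random lists and the limma and camera fits at the preset correlation, also without YK240 day 4, which were planned. Both reference signals given first stem from the Cy5 channel, which the comparison of strains does not use: mtnA and mtnU were not well above background in Cy3 on any YK240 array, while 9 of 9 spots of each were in the Cy5 of the pooled reference. Their computed log2 ratios of Cy3 over Cy5, -5.36 for mtnA and -2.29 for mtnU, have a numerator at background and give no exact difference.

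mtnA and mtnK were close to background in YK240 and well expressed in 168. Failed spots are argued against, since 18 of their 18 spots were well above background in Cy5. A fall of the same size in all genes under the S-box methionine riboswitch is argued against as well. The 9 other such genes tested had a median of -0.28, with mtnU at its bound or at its own value. mtnU forms 1 run of lower neighbours with mtnA and mtnK, so it is no separate comparison, and beside it the lowest of the 9 was -0.72. mtnE, mtnB and mtnD of the same region, at -0.79, -0.75 and -0.83, were not among the 9. A smaller general fall stays open, as 18 of 23 members of the sulfur and methionine list, with mtnA and mtnK, lay below 0. Loss of mtnA and mtnK from the YK240 chromosome, alone or with mtnU, stays open. Of the 18 Cy3 spots, 11 were brighter than 95% of negative control spots, while 1 was well above background. The 18 spots were brighter than 91.0% to 97.7% of these controls, on both sides of that limit. The same share was not taken for other genes at background, and cross-hybridisation and dye bleed-through were not tested, so the count cannot decide. A strain difference through regulation of these genes was not tested.

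The SigB list was lower in YK240, with the widest shift on day 4. That array alone does not carry it, since the median without it was -1.13 and 21 of 27 members fell (limma), with a camera adjusted p = 4.22e-20 (adjusted p = 0.283 with an estimated correlation). Scaling or compression at this expression level is argued against, since the lowest median of 10000 random lists matched on mean expression was -0.20 against -1.30. Within the sigB operon, the last 4 genes rsbV, rsbW, sigB and rsbX had a median of -1.28, and rsbRA, rsbS, rsbT and rsbU of -0.12. Different culture conditions cannot be told apart from the strain, since the labels confound them. The iron and purine lists also lay away from 0, with medians of 0.80 and -0.46. Those of the CcpA and central carbon lists were -0.08 and 0.05. A complete lack of xylose in the YK240 cultures is argued against, although no array labelled as without xylose was there for comparison. sepF behind the xylose-inducible promoter was the brightest gene on all 3 YK240 arrays. xylA and xylB lay above 94.6% and 93.1% of genes or more on every array of both strains. The amount of xylose is not settled by xylA at -0.10, with an interval from -0.86 to 0.66.

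ydcF, ydcG and ydcH rose by 5.01 or more on the log2 scale. Cross-hybridisation of the abundant sepF transcript to single probes is argued against, since 27 of their 27 Cy3 spots were among the brightest 5% of gene spots. A candidate explanation is a transcript that starts between rsbX and ydcF in YK240: tex, the next gene after ydcH, was higher by 1.23 (limma, adjusted p = 0.00614), ydcK behind it by 0.21 (adjusted p = 0.323), and rsbX before ydcF stood at -1.30. Whether such a start comes from the strain's construction or from regulation stays open. Against the pooled reference ydcF and ydcH were higher by 1.99 and 2.30 only, so a start particular to YK240 is not shown.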

How the results depend on the processing

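The alternatives were planned before the data were examined, except leaving out each array together with an estimated list correlation, chosen after seeing the data, with which 0 lists passed. With the day as a replicate block (paired), 0 genes passed (0 higher, 0 lower, 0 at least 2-fold; lowest adjusted p 0.0706), and sepF at 3.50, a size fixed by its equal YK240 values, did not pass (adjusted p = 0.113, against 2.06e-05 to 0.0111 under its other alternatives). The block leaves 1 residual degree of freedom in place of 3. YK240 day 3 has no 168 partner and does not enter the blocked differences. The 104 differences kept their sign, which their non-overlapping arrays fix in advance, at 0.891 to 1.12 times their size. Among lists, the block ended the biofilm call and added the SigM, pyrimidine and branched-chain, tryptophan and histidine lists. It changed no other list call. Leaving out 1 array moved the changed genes to 16 to 298, the higher to 5 to 153, the lower to 11 to 145 and the 2-fold changes to 16 to 165. Where 1 array of 168 was left, its spread was taken from YK240. Of 26 called genes named beside sepF, 11 passed without each array in turn and 15 lost the call at least once. All 104 passed without YK240 day 4. Quantile normalization gave 116 changed genes, median centring 115, the trend 90 (40 higher and 50 lower, against 58 and 46) and the robust fit 97, which ended 2 of the 26 calls, catD and catE. Quantile normalization added the DNA replication list, and leaving out the lowest 25% of genes added the branched-chain list and ended the competence call. Under these, and with the lowest 25% of genes left out, the median of all genes lay between 0.02 and 0.03. Lists past the threshold numbered 10, against 0 with the correlation estimated, 1 by fry's directional test and 9 by its mixed test, which lost 5 of the 10 (iron, PBSX, wall, ribosomal, biofilm) and gained 4 (late division, autolysin, Lia, Bce and Psd, sporulation). The cause was not tested. Between 9 and 14 passed without 1 array. No call reversed. The reference ratio of sepF, 2.06, was 1.64 with median centring in place of loess, and 2.00 to 2.10 without 1 array. The median over probes could not be run on a table with 1 row per gene, and YK240 day 3 left out is the fit without that array. Levels of 578 genes not well above background in YK240 are bounds.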

Other observations

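Genes in this part, and the test of neighbours by shuffling, were chosen after the values were seen. All 6 genes from srfAA to srfT rose, with a median of 2.17, while ycxB behind them differed by -0.15. The regulatory phosphatase gene rapA and its peptide gene phrA both rose by 1.64 (limma, adjusted p = 0.00463 and 0.00614), rapF by 1.81 (adjusted p = 0.0383), rapC by 1.16, phrC by 1.07 and the pectate lyase gene pelA by 2.07 (adjusted p = 0.0228). The sensor kinase gene comP rose by 0.59 (adjusted p = 0.0449), while beside it comQ at 0.80 (adjusted p = 0.0769), the pheromone gene comX at 0.72 (adjusted p = 0.0712) and the response regulator gene comA at 0.96 (adjusted p = 0.0686) did not pass.

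The wapA block was the longest run of changed neighbours, with 13 genes from deaD to wapA lower. The RNA helicase gene deaD fell by 1.40 and yxiM fell by 2.65, while yxiO on the near side rose by 0.73 and yxxF on the far side differed by -0.37 and did not pass. In the methionine salvage region the 5 genes from mtnE to mtnD, read past mtnU, lay between -0.83 and -0.63 and did not pass, and mtnU was at least 1.76-fold lower.

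Changed genes lay next to one another. Of 104, 52 had a chromosomal neighbour changed in the same direction, against a median of 2 and a highest value of 12 in 10000 shuffles of the gene order (permutation p = 0.0001, the smallest these shuffles can give). Shuffling breaks up genes of a shared transcript, so shared transcripts alone could give this result, and it points at no cause. Transcripts were not mapped. Of the 104 changed genes, 36 lay in 7 runs of 3 genes or more.

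The amylase gene amyE stood at 11.74 ± 0.19 in 168 and 9.51 ± 1.08 in YK240, a difference of -2.23 that did not pass (limma, adjusted p = 0.18). On the YK240 arrays 6 of its 9 spots were well above background in Cy3 and 9 of 9 in Cy5. The probes disagreed, in that 1 of the 3 was not well above background in Cy3 on any array.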
